A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

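The series holds 22 libraries of Saccharomyces cerevisiae in 11 groups of 2 replicates. BrdU-IP-Seq, which sequences the DNA made after a thymidine analogue is added, covers 8 libraries in 4 genotype groups. Per the labels' protocols, those cells were arrested with alpha-factor at an OD of about 0.5 and released into hydroxyurea and BrdU, so that label gathers around origins that fire early. RNA-Seq of asynchronous cultures at an OD of about 1 covers 10 libraries in 5 groups. 4C-Seq, which sequences fragments ligated to a bait next to the origin ARS305, covers 4 libraries in 2 groups of alpha-factor-arrested cells. Groups and replicate numbers were taken from the titles alone. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between libraries only.

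Per the submitters' processing notes, reads were processed with Bowtie2 2.2.5, SAMtools 0.1.19 and bedtools 2.24.0 on the R64 build. The deposited files hold counts of overlapping reads per 50 bp bin, with the covered bases beside them, as the 7-column layout of bedtools coverage gives them, and the authors applied no scaling that the values show. An isolated read touches 2 bins at the median in every library, so summed counts come to about 2 for each read, and all depths here are sums of bin counts. In each BrdU file 225777 bins are listed more than once, always with the same count (0 bins with different counts), and each bin was used once. Nuclear bin counts per library range from 1934443 to 12407204 for BrdU-IP-Seq, from 2518554 to 174074267 for RNA-Seq and from 2933643 to 4957520 for 4C-Seq. Intervals and floors cover at most counting error, since PCR copies are not independent molecules.

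Gene names and coordinates come from a RefSeq gene table of the same build. The table holds no strand, origins, centromeres or genome sequence. A centromere was placed in the gap between the innermost genes of the arms, and a chromosome end at the last bin. RNA counts per gene are the sum of the bins whose midpoint lies in exactly 1 gene, which gave 6322 of 6431 genes with bins. After edgeR's filterByExpr 6085 genes were tested. The counting knows no strand, so antisense transcripts are counted with their partners. Near-identical copies such as HHF1 and HHF2, HXT6 and HXT7, PHO11 and PHO12, the FLO genes and repeats near chromosome ends share reads, and their values are uncertain.

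Because no origin table was available, BrdU windows of 5 kb were centred on local maxima of the mean profile of all 8 libraries, smoothed over 1050 bp, with maxima under 2.5 kb apart merged. Of 1482 maxima, 328 windows had a mean density of at least 2 times the genome median and were kept. The ribosomal DNA on chromosome XII (451075 to 489969) was left out of the windows. For 4C-Seq the planned XbaI fragments could not be made without a genome sequence, so windows of 10 kb, which had been set down as a second choice, were used in their place. Windows within 20 kb of the bait bin (chromosome III, 38951 to 39000) were left out, and 1189 windows were tested.

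Tests used edgeR 4.0.16 (quasi-likelihood, TMM scaling) with 1 fit over all libraries of an assay and group as the only term, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the features tested, at a threshold of 0.05. Gene lists and window classes were tested two-sided with limma's camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists and the 4 main RNA comparisons together, over the classes and 3 BrdU contrasts, or over the 5 classes of 4C windows. A correlation estimated from the data was the alternative. Shares in 4C-Seq were compared with an exact two-sided permutation test, whose smallest possible p with 2 against 2 libraries is 0.333. Alternatives were DESeq2 1.42.0, limma on quantile-normalized values with a prior count of 1, scaling by library totals, other count filters, other window widths, genes extended by 100 bp, a replicate block and leaving out each library in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

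The RNA libraries split by replicate number in their technical properties. Genes took 69.8% to 78.3% of nuclear counts in the replicate 1 libraries and 61.3% to 66.7% in the replicate 2 libraries. For this reason a fit with the replicate number as a block was made for every RNA result. Its values, or those within each number, are given where they change the call of a list, and for some genes. Counts of list members that passed with the block are given for some lists only. The numbers do not mark a stated pairing: of the 10 pairs of RNA groups, 9 had deviations from the group means that correlated at 0.36 to 0.75 across genes, and 1 pair had 0.09. The common coefficient of variation in edgeR was 0.42 without the block and 0.22 with it. The RNA fit without the block therefore counts this split as spread between libraries. In that fit 5 to 172 of 6085 genes per comparison had an unadjusted p under 0.05, always below a 0.05 share of the genes tested. Its p-values are thus conservative, and a low count does not show that groups are alike. Blocked values for the other assays are given only with the alternatives.

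The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. In each of the 4 main RNA comparisons the rule names FKH1 and FKH2, and always CLB2, CLB1, SWI5 and CDC20; 1 further gene of that rule is not reported here. It then takes the 5 largest rises and 5 largest falls by fitted fold change among genes past the threshold, with both replicates of one group above both of the other and a mean of at least 10 CPM (counts scaled for library size) in the higher group. FKH1, FKH2 and the strain markers URA3, LEU2, TRP1, HIS3, LYS2, ADE2, MET15 and BAR1 were kept out of that ranking and serve as genotype checks. For each list the rule also names the 2 members with the lowest p. The other RNA comparisons take the 2 largest rises and falls. BrdU contrasts take ARS305, ARS607 and ARS1 where kept, with the 5 largest rises and falls, and 4C-Seq takes the 3 largest rises and falls. Where fewer pass, those that pass are named. The text gives only some of the list members, and further genes that passed only with the block were chosen after their values were seen.

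The 16 lists are the CLB2 cluster, M/G1 transition genes, M/G1 Mcm1 ECB genes, G1/S SBF-MBF targets, S/G2 Hcm1 targets, core histones, origin licensing and firing factors, flocculins, a-specific genes, alpha-specific genes, haploid-specific genes, meiosis genes, stress response genes, ribosome biogenesis, the phosphate (PHO) regulon, and glucose-repressed and diauxic genes. Of 252 members 250 were tested. BAR1 had 0 counts, and PHO84 had no bins outside overlapping genes.

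Which forkhead gene a library held was read from its coverage. CPM in these checks and for the strain markers are scaled by library totals (counts in genes for RNA), whereas CPM of tested genes and windows also carry the TMM factors, so the same gene can have 2 values. A gene counted as held in RNA at 10 CPM or more, and in BrdU at 0.25 or more of the mean density of the 2 kb on either side. For FKH2 the part of 600 bp at the 3′ end (chromosome XIV, 495701 to 496300) was used, because the rest of the gene kept coverage in some libraries that lack this part. These thresholds and the part were chosen after the values were seen. No library was moved to another group. A fold against a group at 0 was computed against a floor of 3 bin counts per library. Since a read gives about 2 bin counts, this floor is fewer than 3 reads, and the fold is no strict lower bound.

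The planned comparisons of 2 groups were checked on simulated counts drawn from the real means with known changes. The difference of the dsm effects, the added contrasts and the ribosomal DNA test were not simulated. For the RNA comparisons the simulation changed 200 of 6085 genes, and 0% to 4% of 2-fold changes, 24% to 36% of 4-fold changes, 66% to 82% of 8-fold changes and 78% to 94% of 16-fold changes were recovered. For the BrdU contrasts it changed 60 of 328 windows, and 35% to 75% of 1.5-fold changes, 90% of 2-fold changes and 100% of 4-fold changes were recovered. For the 4C comparison it changed 200 of 1189 windows, and 0% of 2-fold, 7.46% of 4-fold and 34.8% of 8-fold changes were recovered. False calls made up 1.85% to 10.1% of the calls. The draws were independent between genes and held no replicate effect shared across them, so recovery in the data can be lower. FKH2 in the double deletion fell far beyond 16-fold and did not pass in edgeR without the block. In BrdU up to 248 of 328 windows were called in the data, and scaling at such a share of changes was not simulated. Not analysed here were matches to forkhead motifs, which need the genome sequence, and the base changes of the dsm alleles, which coverage cannot show.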

Results

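The series measured replication, transcripts and chromosome contacts in budding yeast that lack or carry altered copies of the forkhead transcription factor genes FKH1 and FKH2. The labels name strains with 1 gene deleted (fkh1Δ, fkh2Δ), strains with a dsm allele of one gene beside a deletion of the other (fkh1-dsm fkh2Δ, fkh2-dsm fkh1Δ) and, for RNA-Seq, the double deletion. BrdU-IP-Seq has 8 libraries with 1934443 to 12407204 nuclear bin counts, RNA-Seq has 10 with 2518554 to 174074267, and 4C-Seq has 4 with 2933643 to 4957520. Every group has 2 replicates. Values are means ± SD of n = 2 libraries unless single libraries are given. No unmodified strain was included. CPM in the checks of FKH1, FKH2 and the markers are scaled by library totals, and CPM in the comparisons also by TMM, so values of the same gene differ between them.

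The targeted genes were read first in every RNA and BrdU library, because they check the labels. FKH1 (YIL131C, chromosome IX, 100781 to 102235) had 0 counts in both RNA libraries labelled fkh2Δ, although that label keeps it. The 3′ part of FKH2 (YNL068C, chromosome XIV, 495701 to 498289), the gene that label deletes, stood at 94.9 and 52.9 CPM there. The libraries labelled fkh1Δ had 2 and 0 counts in FKH1 and 90.6 and 66.3 CPM in the 3′ part of FKH2, which fits their label. FKH1 stood at 68.0 and 99.9 CPM in the libraries labelled fkh1-dsm fkh2Δ, and the 3′ part of FKH2 at 0.0841 and 0.0375 CPM. In the libraries labelled fkh2-dsm fkh1Δ, FKH1 stood at 78.8 and 113 CPM and the 3′ part of FKH2 at 0.149 and 0.0844 CPM, the reverse of the label. The double deletion had 5 and 0 counts in FKH1 and 9 and 0 counts in the 3′ part of FKH2.

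In the BrdU libraries, whose input is genomic DNA, coverage of FKH1 relative to its flanks was 0.0667 and 0.0503 where the label was fkh2Δ, and 0.802 and 0.899 where it was fkh1Δ. The 3′ part of FKH2 ran the other way, at 0.649 and 0.340 under the label fkh2Δ and at 0.0230 and 0.00415 under the label fkh1Δ. In the libraries labelled fkh1-dsm fkh2Δ, FKH1 stood at 0.536 and 0.500 and the 3′ part of FKH2 at 0.00985 and 0.00913. In those labelled fkh2-dsm fkh1Δ, FKH1 stood at 0.177 and 0.0839, below the level taken as held, and the 3′ part of FKH2 at 0.655 and 0.531. By coverage, 8 of 18 libraries went against their label, 4 of the 10 RNA libraries and 4 of the 8 BrdU libraries. The 4C libraries had only 2 to 8 counts in FKH1 and could not be checked. Groups were kept as labelled, and each comparison names the gene that each side held. Coverage cannot show whether a held gene carries the dsm changes, so which libraries hold a dsm allele rests on the labels alone. For FKH2 this refers to the 3′ part alone. The rest of FKH2 kept coverage in all 8 BrdU libraries and in the RNA libraries labelled fkh1-dsm fkh2Δ, so a group said to lack FKH2 may hold part of it.

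**Figure D1:**
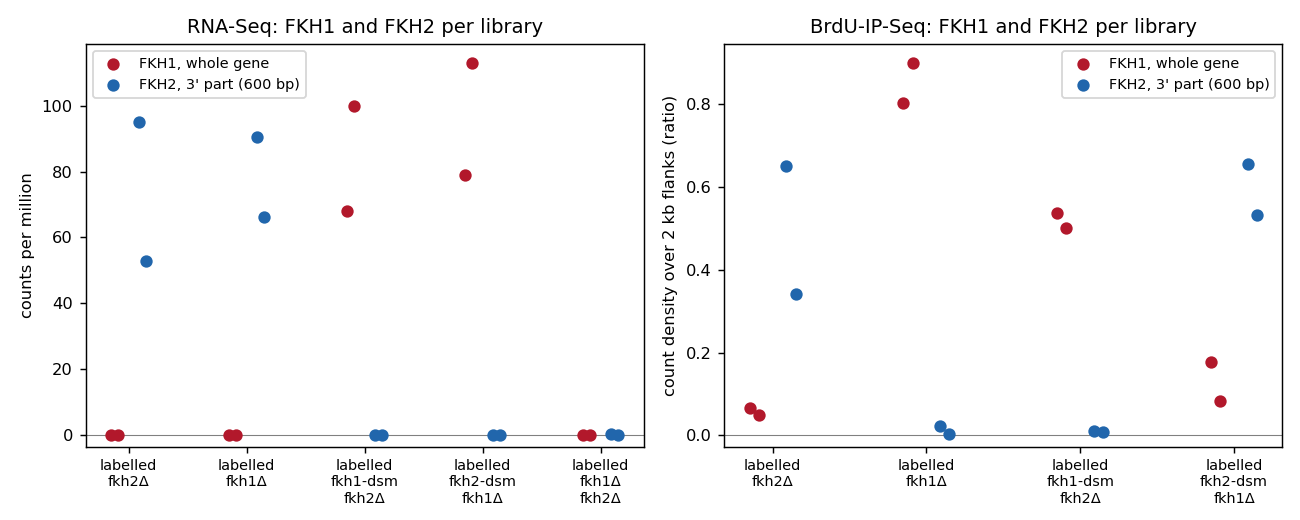
Coverage of FKH1 and of the 600 bp at the 3′ end of FKH2 in each library, as CPM in RNA-Seq and as density relative to the 2 kb flanks in BrdU-IP-Seq. In RNA-Seq FKH1 stands at 68.0 to 113 CPM in the 4 libraries with a dsm label and at 0 or close to it in the other libraries.

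Strain markers differed between and within RNA groups. URA3, whose product makes uracil, stood at 79.6 and 128 CPM in the libraries labelled fkh2-dsm fkh1Δ and between 663 and 2470 CPM in the 8 others. TRP1 differed between the replicates labelled fkh2Δ, at 74.6 and 12.6 CPM. It was 66.7 and 62.2 CPM in those labelled fkh1-dsm fkh2Δ and 10.4 to 19.4 CPM in the 6 remaining libraries. URA3 also differed between the replicates labelled fkh2Δ, at 1570 and 669 CPM, and was 663 and 693 CPM in those labelled fkh1Δ. Whether the 2 RNA libraries labelled fkh2Δ come from the same strain was not tested. Means, SDs and p-values with this RNA label treat them as replicates and may mix strains. BAR1, which encodes a protease that breaks down alpha-factor, had 0 counts in all 10 RNA libraries.

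The comparison of the double deletion with each single deletion asks which transcripts depend on having a forkhead gene at all. By coverage the libraries labelled fkh2Δ and those labelled fkh1Δ both held FKH2 and lacked FKH1, so both comparisons set no forkhead gene against FKH2. CTS1, which encodes the chitinase that separates daughter from mother cells, fell from 789 ± 49.3 CPM in the libraries labelled fkh2Δ to 100 ± 7.55 CPM, 7.87-fold lower (log2 fold change −2.98, SE 0.29, edgeR adjusted p = 0.0205). Against the libraries labelled fkh1Δ, at 846 ± 139 CPM, it was 8.44-fold lower (adjusted p = 0.0164). LEU1, which encodes an enzyme of leucine synthesis, rose from 164 ± 25.2 to 2430 ± 851 CPM (log2 fold change 3.89, SE 0.36, adjusted p = 0.0205) and stood at 177 ± 4.46 CPM under the label fkh1Δ (3.78, adjusted p = 0.0164). BAT1, the mitochondrial branched-chain aminotransferase gene, rose from 197 ± 18.4 to 1420 ± 205 CPM (2.85, SE 0.31, adjusted p = 0.0328), with 214 ± 15.3 CPM under the label fkh1Δ (2.73, adjusted p = 0.0429). Against the label fkh2Δ, within replicate 1 and replicate 2 alone the log2 fold changes were −3.12 and −2.83 for CTS1, 3.64 and 4.06 for LEU1, and 2.60 and 3.09 for BAT1.

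These 3 genes (2 higher, 1 lower) were all that passed in edgeR in each of the 2 comparisons. With the replicate block 44 genes passed against the label fkh2Δ (23 higher, 21 lower) and 31 against the label fkh1Δ (10 higher, 21 lower), and DESeq2 gave 23 in each. The calls without the block were fragile. Leaving out any 1 of the 10 libraries ended the CTS1 call against the label fkh2Δ (adjusted p 0.0518 to 0.313), with a log2 fold change that stayed between −3.14 and −2.90. The LEU1 call there held only without replicate 1 of the double deletion, and the BAT1 call ended without any 1 of them. The shared group raises the overlap of both comparisons by itself. Independent lists would share 0.000657 higher and 0.000164 lower genes, 20 simulated draws without effects shared 0, and the fold changes correlated at 0.82 across genes against 0.52 simulated, with a covariance of 0.466 against 0.277.

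**Figure D2:**
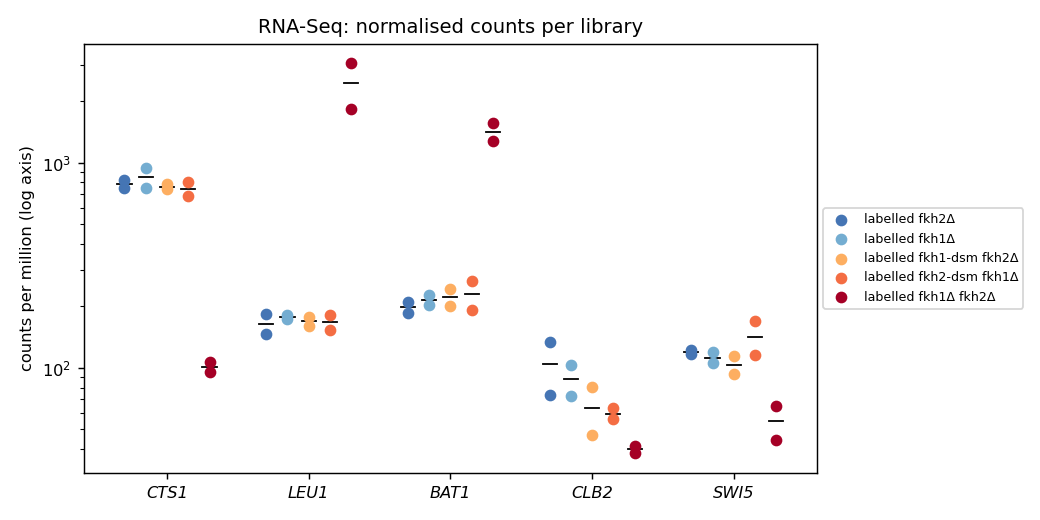
CPM of CTS1, LEU1, BAT1, CLB2 and SWI5 in each RNA library of the 5 labelled groups on a log axis, with a dash at each mean. CTS1 lies at 100 CPM and LEU1 at 2430 CPM on average in the double deletion, away from the 4 other groups.

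Cell-cycle genes that forkhead proteins are known to regulate were lower in the double deletion, most of them without passing. CLB2, the main mitotic cyclin gene, stood at 39.9 ± 2.44 CPM against 104 ± 42.4 under the label fkh2Δ (log2 fold change −1.37, SE 0.39, edgeR adjusted p = 1, blocked 0.108) and 87.7 ± 21.5 under the label fkh1Δ (−1.13, adjusted p = 0.999, blocked 0.226). CLB1, its paralog, stood at 22.3 ± 0.0379 CPM against 56.7 ± 14.0 and 61.3 ± 11.0, and passed with the block (−1.26, adjusted p = 0.0361, and −1.38, adjusted p = 0.0215) but not without it (adjusted p = 1 and 0.999). SWI5, a transcription factor gene that acts at mitotic exit, stood at 54.7 ± 14.4 CPM against 119 ± 3.31 and 112 ± 10.4, with blocked adjusted p-values of 0.0484 and 0.0819. CDC20, which encodes an activator of the anaphase-promoting complex, differed by −0.51 and −0.64 on the log2 scale and passed in neither fit. FKH2 itself had 0.345 ± 0.488 CPM in the double deletion against 349 ± 156 and 340 ± 128, with adjusted p = 0.0728 and 0.0683 without the block and 7.45e-06 and 7.3e-06 with it.

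Of the genes that passed only with the block, several act like CTS1 in separating daughter cells. EGT2 stood at 60.3 ± 7.29 CPM against 416 ± 54.9 under the label fkh2Δ (blocked log2 fold change −2.76, adjusted p = 0.00167), and DSE2 at 31.3 ± 9.08 against 179 ± 17.8 (−2.56, adjusted p = 0.000841). The same fit called DSE4 (−2.58), SCW11 (−2.41), AMN1 (−1.79), SUN4 (−1.68) and DSE1 (−1.65) lower. OAC1, which encodes a mitochondrial carrier linked to leucine synthesis, was higher at 205 ± 154 CPM against 8.69 ± 1.67 (4.20, adjusted p = 0.000693). ILV3 (1.68), LEU4 (1.48) and ILV2 (1.42) of the same pathway, and ARG1 (2.82), were also higher. Against the label fkh1Δ OAC1 (3.22) and ILV3 (1.52) passed with the block, while LEU4, ILV2 and ARG1 did not. HTB2 (−1.72), HHF2 (−1.49), HTA2 (−1.34) and HTA1 (−1.15) were lower among the histone genes. None of these passed in the fit without the block.

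Among the lists, the M/G1 transition genes stood furthest apart in the double deletion. Their median log2 fold change was −1.28 against the label fkh2Δ and −1.24 against the label fkh1Δ, with 22 of 24 members lower in each. CTS1 alone fell among all genes tested, 11 members fell when adjusted over the list alone in each comparison, and 9 fell with the block. Camera gave an adjusted p of 2.12e-33 and 1.19e-35 with the preset correlation, and adjusted p = 0.0177 with an estimated correlation in both. The medians within the replicate numbers were −1.23 and −1.24 against the label fkh2Δ. With both the block and an estimated correlation the adjusted p was 0.0723, so the call did not hold in that fit. This list passed in both comparisons, and no other list passed with an estimated correlation in any of the 4 main comparisons.

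The CLB2 cluster, genes of mitosis driven by Fkh2 and Mcm1, had medians of −0.50 and −0.54 in the double deletion, with 26 of 30 members lower in each. Without the block no member passed over all genes, and 6 and 4 passed when adjusted over the list alone. With the block 3 fell over all genes in each comparison and 10 and 13 when adjusted over the list alone, among them CLB1 and CDC5, a kinase gene of mitosis. HOF1, which acts in cytokinesis, led it at −1.64 (adjusted p = 0.759), and HST3, a histone deacetylase gene, stood at −1.03 (adjusted p = 0.989; against the label fkh1Δ blocked adjusted p = 0.0489). The list's preset p was 1.24e-09 and 7.67e-11, but adjusted p = 0.111 with an estimated correlation in both. Core histones had medians of −0.89 (adjusted p = 0.000152) and −1.02 (0.000417), and adjusted p = 0.312 and 0.344 with an estimated correlation. Ribosome biogenesis genes had medians of −0.76 (22 of 22 lower, adjusted p = 1.18e-07) and −0.74 (9.76e-07), and adjusted p = 0.583 with an estimated correlation in both. When adjusted over the list alone, 16 and 13 of them fell with the block and 0 without it. The double deletion also had the lowest ribosomal DNA share of the RNA counts within each replicate number (7.89% and 15.38%) and the highest share in genes (78.3% and 66.7%), and whether this moves the list was not tested. Without replicate 1 of the double deletion the ribosome biogenesis medians were −0.44 and −0.43. Without replicate 2 of the label fkh2Δ the first of them was −0.09, and without replicate 2 of the label fkh1Δ the second was 0.05. Without the latter library the histone median was −0.40.

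The remaining lists in the double deletion were smaller shifts, given against the label fkh2Δ first and the label fkh1Δ second. The Mcm1 ECB genes had −0.20 and −0.20 (adjusted p = 0.0229 and 0.0180, with the block 0.0539 in the first; adjusted p = 0.312 with an estimated correlation in both), led by FAR1, which arrests cells exposed to pheromone, at −1.06 and −1.23. Against the label fkh1Δ 1 member of this list passed when adjusted over the list alone. Flocculins had 0.63 and 0.68 (0.0183 and 0.00549; adjusted p = 0.583 with an estimated correlation in both). Meiosis genes had 0.48 and 0.36 (0.0164 and 0.0181; adjusted p = 0.583 with an estimated correlation in both), and glucose-repressed genes 0.27 and 0.28 (0.0105 and 0.0261; adjusted p = 0.694 and 0.765 with an estimated correlation). Alpha-specific genes had 1.11 (0.0455, with the block 0.108; adjusted p = 0.499 with an estimated correlation) and 1.16 (0.101), from genes of few counts. The G1/S targets (−0.22, −0.12), Hcm1 targets (0.01, −0.02), origin factors (−0.13, −0.16), a-specific genes (−0.26, −0.42), haploid-specific genes (−0.36, −0.39), stress response genes (0.18, 0.26) and the phosphate regulon (0.03, 0.06) did not pass in either comparison. Stress response genes alone did so with the block (medians 0.60 and 0.76, adjusted p = 0.00169 and 0.000204), but not with an estimated correlation as well (adjusted p = 0.63 and 0.614 with an estimated correlation). Several of these calls ended when 1 library was left out, which also unbalances the replicate numbers between the groups. Within replicate 1 and replicate 2 the flocculin medians against the label fkh2Δ were 0.58 and 0.65. Meiosis genes had 0.47 and 0.63 there, and glucose-repressed genes 0.16 and 1.32. Alpha-specific genes had 0.90 and 0.25, and Mcm1 ECB genes −0.01 and −0.49. The flocculin, meiosis and glucose-repressed calls ended without replicate 1 of the double deletion, at medians of 0.26, −0.01 and −0.03 against the label fkh2Δ. The alpha-specific median was −0.17 without that library and 4.83 without replicate 1 of the label fkh2Δ, and neither passed. The Mcm1 ECB calls ended without either double deletion library (−0.51 and −0.28 against the label fkh2Δ, −0.51 and −0.15 against the label fkh1Δ), and without replicate 2 of the label fkh2Δ (−0.10) or of the label fkh1Δ (−0.15).

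The comparison of the label fkh1-dsm fkh2Δ with fkh2Δ was designed to show what the dsm allele of FKH1 changes in transcripts. By coverage it set FKH1 against FKH2, so it does not isolate that allele. FKH1 stood at 84.0 ± 22.6 CPM before TMM scaling, 83.3-fold the floor of 3 bin counts per library under the label fkh2Δ, where it had 0 counts (edgeR adjusted p = 0.0387, blocked 5.41e-05). It was the only gene that passed in edgeR with or without the block and in DESeq2, with 13 genes at an unadjusted p under 0.05 (98 with the block). The FKH1 call ended when any of 8 libraries was left out (adjusted p up to 0.854), and when genes were extended past their 3′ ends (log2 fold change 4.75, adjusted p = 1). FKH2 as a whole had 107 ± 72.8 CPM against 349 ± 156 (log2 fold change −1.71, adjusted p = 1), while the rest of the gene beside its missing 3′ part kept 135 and 54.7 CPM before TMM scaling. CLB2 stood at 63.6 ± 23.6 CPM against 104 ± 42.4 (−0.70, SE 0.39), and CLB1 (−0.02), SWI5 (−0.20) and CDC20 (−0.18) differed by less, all with adjusted p = 1. MRH1, a plasma membrane protein gene of the CLB2 cluster, stood at 212 ± 87.7 CPM against 517 ± 34.8 (−1.28, SE 0.48, adjusted p = 1).

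Of the lists in that comparison, 3 passed with the preset correlation and none with an estimated one. The CLB2 cluster had a median of −0.20 with 23 of 30 members lower (4.33e-05; adjusted p = 0.286 with an estimated correlation). The a-specific genes had 0.39 (0.00268; adjusted p = 0.479 with an estimated correlation) and the phosphate regulon 0.25 (0.0261; adjusted p = 0.519 with an estimated correlation). The phosphate median was 0.05 without replicate 2 of the label fkh2Δ, and the a-specific median was −0.13 without replicate 2 of the label fkh1-dsm fkh2Δ. No member of any list passed over all genes (13 genes in all at an unadjusted p under 0.05), and 0 members passed when adjusted over the list alone (with the block 1, in the CLB2 cluster). The other 13 medians did not pass: M/G1 transition genes −0.01, Mcm1 ECB genes 0.01, G1/S targets −0.05, Hcm1 targets 0.14, core histones −0.04, origin factors 0.01, flocculins 0.13, alpha-specific genes 0.10, haploid-specific genes 0.02, meiosis genes −0.11, stress response genes −0.17, ribosome biogenesis −0.15 and glucose-repressed genes −0.01.

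The comparison of the label fkh2-dsm fkh1Δ with fkh1Δ was designed to show what the dsm allele of FKH2 changes. By coverage it also set FKH1 against FKH2. FKH1 stood at 87.6 ± 12 CPM against 0.0516 ± 0.0730 (edgeR adjusted p = 0.0207, blocked 5.94e-06) and was the only gene that passed without the block. That call ended when any of 7 libraries was left out (adjusted p up to 0.174), and when genes were extended past their 3′ ends (log2 fold change 4.68). FKH2 had 0.416 ± 0.419 CPM against 340 ± 128 and passed only with the block (adjusted p = 1.11e-06 against 0.108). With the block 2 genes passed and DESeq2 gave 3. Without the block 17 genes had an unadjusted p under 0.05, and with it 115. CLB2 stood at 59.8 ± 5.31 CPM against 87.7 ± 21.5 (log2 fold change −0.55, SE 0.38), and CLB1 (0.17), SWI5 (0.34) and CDC20 (−0.06) differed by less, all with adjusted p = 1. PHO5, an acid phosphatase gene induced by phosphate starvation, stood at 1070 ± 510 CPM against 316 ± 205 (1.76, SE 0.66, adjusted p = 1), and its log2 fold change was 0.62 within replicate 1 and 3.06 within replicate 2.

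Of the lists in that comparison, 8 passed with the preset correlation and none with an estimated one. Core histones had a median of −0.68 with 10 of 10 members lower (1.36e-07; adjusted p = 0.187 with an estimated correlation) and −0.28 without replicate 2 of the label fkh1Δ, which ended the call. No histone gene passed over all genes, and 6 fell with the block when adjusted over the list alone. HTB1 led them at 168 ± 3.70 CPM against 271 ± 40.4 (−0.69, adjusted p = 1). Ribosome biogenesis genes had −0.58 with 22 of 22 lower (9.76e-07; adjusted p = 0.583 with an estimated correlation), but their medians within the replicate numbers were 0.10 and −0.97, and 0.21 without replicate 2 of the label fkh1Δ. The phosphate regulon had 0.28 (1.12e-06; adjusted p = 0.187 with an estimated correlation). The a-specific genes had 0.57 (2.81e-05; adjusted p = 0.312 with an estimated correlation) and 0.18 without replicate 2 of the label fkh1Δ. Meiosis genes had 0.35 (0.000759; adjusted p = 0.551 with an estimated correlation), with −0.21 and 1.00 within the replicate numbers. G1/S targets had −0.20 (0.00823; adjusted p = 0.694 with an estimated correlation) and 0.17 without replicate 2 of the label fkh1Δ. Alpha-specific genes had 0.62 (0.0183; adjusted p = 0.404 with an estimated correlation) and flocculins 0.19 (0.0267; adjusted p = 0.583 with an estimated correlation), and without replicate 2 of the label fkh1Δ they were 0.44 and −0.08 and did not pass. The CLB2 cluster (−0.11), M/G1 transition genes (−0.19), Mcm1 ECB genes (−0.09), Hcm1 targets (0.01), origin factors (−0.04), haploid-specific genes (−0.01), stress response genes (0.16) and glucose-repressed genes (0.10) did not pass.

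The stress response, ribosome biogenesis and glucose-repressed lists follow growth conditions, and here their medians without the block changed with the library left out. Leaving out 1 library also unbalances the replicate numbers between the groups. An effect of that library cannot be told apart from the split by replicate number in these fits. For the label fkh1-dsm fkh2Δ against fkh2Δ the stress response median was 1.92 without replicate 1 of fkh2Δ and −0.89 without replicate 2, and both passed. It was −2.88 without replicate 1 of fkh1-dsm fkh2Δ and 0.56 without replicate 2. Ribosome biogenesis was −0.61 and 0.47 without the 2 libraries labelled fkh2Δ in turn. For the label fkh2-dsm fkh1Δ against fkh1Δ the stress response median was 2.5 and −0.67 without the 2 libraries labelled fkh1Δ, and glucose-repressed genes 0.79 and −0.47. With the block the stress response list passed at −0.29 (adjusted p = 0.0023) and 0.41 (2.6e-06) in the dsm comparisons (adjusted p = 0.63 and 0.521 with an estimated correlation). Within replicate 1 and replicate 2 the stress response medians were −0.21 and −0.16 in the first dsm comparison and 0.05 and 0.72 in the second. Ribosome biogenesis had −0.02 and −0.22 in the first and 0.10 and −0.97 in the second. Glucose-repressed genes had 0.17 and −0.41, then 0.06 and 0.05. Without the block the directions depended on which libraries were included, and so on the balance of replicate numbers.

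Against the double deletion, both dsm labels kept CTS1 high and LEU1 and BAT1 low. By coverage, with FKH2 judged by its 3′ part, these comparisons set FKH1 against no forkhead gene. Under the label fkh1-dsm fkh2Δ the rest of FKH2 still kept 135 and 54.7 CPM before TMM scaling. CTS1 stood at 761 ± 30.9 CPM under the label fkh1-dsm fkh2Δ (log2 fold change 2.93, SE 0.29, edgeR adjusted p = 0.0197) and 747 ± 82.1 under the label fkh2-dsm fkh1Δ (2.90, adjusted p = 0.0203), each against 100 ± 7.55. LEU1 was lower by −3.85 and −3.87 and BAT1 by −2.68 and −2.64 on the log2 scale (adjusted p = 0.0197 and 0.0203 for LEU1, 0.0362 and 0.0401 for BAT1). With FKH1, 4 genes passed under the first label and 6 under the second, where DSE1, a daughter cell wall gene, was higher at 127 ± 14.6 CPM against 30.7 ± 0.669 and the marker URA3 lower at 94.6 ± 20.7 against 1830 ± 677. The blocked fit called 35 and 21 genes, and DESeq2 22 and 19. Both BAT1 calls ended when any 1 library was left out, and at least 5 of 10 such fits ended each of the others. The BAT1 log2 fold changes stayed at −2.84 to −2.47 and −2.85 to −2.38 in these fits.

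Between the libraries labelled fkh1Δ and fkh2Δ no gene passed in edgeR, with the block or in DESeq2. In edgeR 5 genes had an unadjusted p under 0.05, and 22 with the block. Both lie below a 0.05 share of the 6085 tested, so these counts do not measure how alike the groups are. FKH2 stood at 340 ± 128 CPM against 349 ± 156 (log2 fold change −0.04, SE 0.81), as both held it. The dsm labels were also compared with each other after their coverage was seen, since both held FKH1. No gene passed in edgeR and 54 had an unadjusted p under 0.05 (396 with the block), while URA3 and FKH2 passed with the block, and DESeq2 gave 2 genes.

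In BrdU-IP-Seq the comparison of the label fkh1-dsm fkh2Δ with fkh2Δ asks where early replication depends on the dsm allele of FKH1, and by coverage it set FKH1 against FKH2. The window at ARS305, an early origin on chromosome III (36751 to 41750, between APA1 and YCL049C), rose from 1060 and 1680 CPM to 11200 and 11500 CPM, 8.30-fold (log2 fold change 3.05, SE 0.21, edgeR adjusted p = 5.41e-10). ARS607 on chromosome VI (197051 to 202050, between ROG3 and PES4) rose from 1970 and 2210 to 10900 and 11200 CPM (2.40, SE 0.15, adjusted p = 1.52e-10). ARS1 on chromosome IV (459951 to 464950, over TRP1) did not pass (−0.19, adjusted p = 0.37), except with quantile normalization, where it was lower (−0.59). The largest rise lay on chromosome XV at 1050951 to 1055950, between RDR1 and FRE3, from 459 and 470 to 8890 and 9260 CPM (4.29, SE 0.14, adjusted p = 1.07e-14). It was followed by the left end of chromosome VI (1 to 3350, 3.72), chromosome XII at 3301 (3.39), the window over BUL1 (3.26) and that over EAP1 (3.20). The largest fall lay on chromosome XIV at 410101 to 415100, between YNL115C and RPC19, from 4820 and 4610 to 526 and 457 CPM (−3.27, SE 0.13, adjusted p = 4.13e-13). Falls at SMC6 (−2.92), LCD1 (−2.80), chromosome XV at 678601 (−2.78) and chromosome IV at 1107651 (−2.77) followed.

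Of 328 windows 242 passed, 119 higher and 123 lower, and 80 and 78 of these changed beyond 2-fold. Windows within 30 kb of a chromosome end rose in 38 of 42 cases, with a median of 2.37 (camera adjusted p = 3.02e-13; adjusted p = 0.38 with an estimated correlation). Those within 30 kb of a centromere fell in 32 of 56 cases and rose in 3, with a median of −0.58 (0.000806; adjusted p = 0.48 with an estimated correlation). Of the 42 windows near ends, 28 lay within 5 kb of an end and 12 at 5 to 15 kb, where repeats share reads. Windows were kept by their mean over all 8 libraries, so some near ends may have been kept through the dsm libraries. The classes were not retested without that filter. Scaling by library totals in place of TMM moved the median of all windows from −0.18 to −0.01, and 136 of 245 called windows were then higher.

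The comparison of the label fkh2-dsm fkh1Δ with fkh1Δ asks the same of the FKH2 allele, and by coverage it set FKH2 against FKH1. ARS305 rose from 1350 and 2110 to 3820 and 3350 CPM (log2 fold change 1.06, SE 0.20, edgeR adjusted p = 0.000259; with no minimum density 0.94, adjusted p = 0.0712) and ARS607 from 2500 and 2810 to 8290 and 7340 CPM (1.56, SE 0.15, adjusted p = 1.44e-07). ARS1 did not pass (0.35, adjusted p = 0.126), except in DESeq2 (adjusted p = 0.0447). The largest rise was at DCG1 on chromosome IX (409601 to 414600; 2.17, SE 0.14, adjusted p = 4.22e-09), followed by the right end of chromosome VIII (1.80) and chromosome XV at 1050951 (1.79). The largest falls were on chromosome XII between SFP1 and SEI1 (−1.48), on chromosome IV between SSB1 and HO (−1.41) and at SMC6 (−1.37). In all 188 windows passed, 85 higher and 103 lower. Near chromosome ends 40 of 42 windows rose, with a median of 1.34 (1.37e-20; adjusted p = 0.38 with an estimated correlation). The limits given above for these windows, their position and how they were kept, hold here too. Near centromeres 5 rose and 7 fell, with a median of 0.20 (adjusted p = 0.513). The 2 contrasts share no libraries, and 76 windows were higher and 82 lower in both, against 30.8 and 38.6 for independent lists, with 2 in opposite directions and a correlation of 0.82 across windows, which are not independent replicates.

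**Figure D3:**
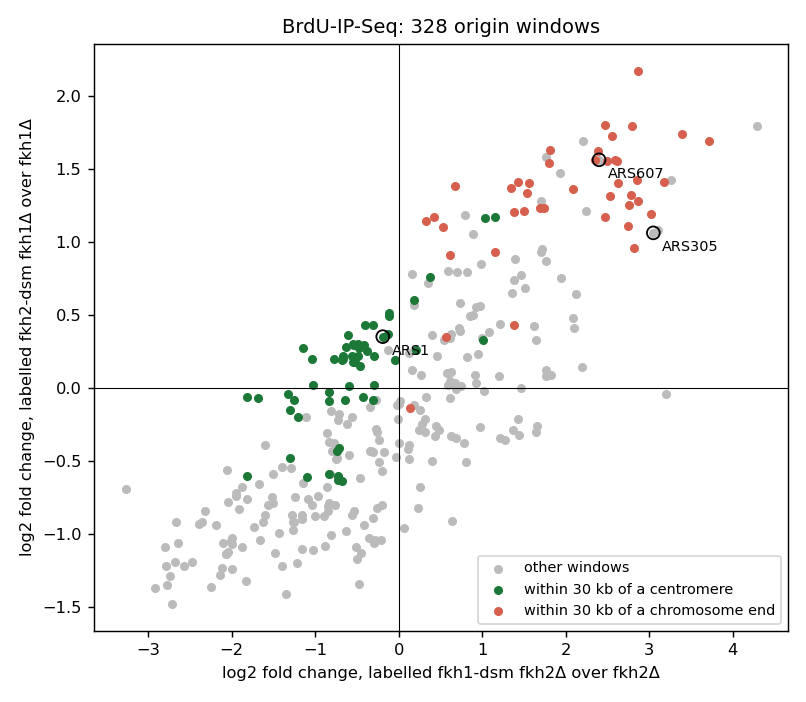
Log2 fold change of each of 328 BrdU windows for the label fkh1-dsm fkh2Δ over fkh2Δ (x axis) and fkh2-dsm fkh1Δ over fkh1Δ (y axis), with windows within 30 kb of a centromere in green and of a chromosome end in red. ARS305 (3.05 and 1.06) and ARS607 (2.40 and 1.56) lie above 0 on both axes, and ARS1 lies at −0.19 and 0.35.

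The difference between the dsm effects was tested itself. ARS305 responded more under the label fkh1-dsm fkh2Δ, by 2.0 on the log2 scale (SE 0.28, edgeR adjusted p = 1.91e-05), and ARS607 by 0.84 (SE 0.20, adjusted p = 0.00295; with no minimum density 1.51, adjusted p = 0.0681), while ARS1 did not differ past the threshold (−0.54, adjusted p = 0.112; past it at −0.71 without replicate 1 of the label fkh2Δ and at −0.61 with quantile normalization). With the deletion labels exchanged, so that each dsm label met the deletion label that held the same forkhead gene by coverage, the difference was 1.33 for ARS305 (adjusted p = 0.00132) but 0.15 for ARS607 (adjusted p = 0.576) and −0.53 for ARS1 (adjusted p = 0.122), with 141 windows past the threshold. This contrast was added after coverage was seen. The ARS607 call therefore depends on the deletion labels. With the labels as given, EAP1 (3.24) differed most upward and chromosome XIV at 410101 (−2.57) most downward. In all 126 of 328 windows passed, 75 with a larger and 51 with a smaller value under the first label. Library-total scaling moved that split, with 101 of 139 windows larger (72.7% against 59.5%), quantile normalization gave 77 of 174 and DESeq2 76 of 158. Library totals moved the median of all windows from 0.04 to 0.24.

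By coverage the libraries labelled fkh1Δ and fkh2Δ held FKH1 and FKH2, the reverse of what their labels keep, so the sign below follows the labels only. The window between STB6 and OSI1 on chromosome XI (299751 to 304750) had 7650 and 8830 CPM under the label fkh1Δ against 3380 and 3960 (log2 fold change 1.17, SE 0.17, edgeR adjusted p = 0.000518). Chromosome X at 201701 (0.98), RCI37 (0.78), chromosome VIII at 445651 (0.75) and chromosome XVI at 631301 (0.73) followed, the last not called without replicate 1 of the label fkh2Δ (0.61) or replicate 2 of the label fkh1Δ (0.62). In all 8 windows passed, all higher, and 46 had an unadjusted p under 0.05. Library totals gave 18, and with no minimum density 123 windows passed, 67 higher and 56 lower, so the number that differ depends on the windows tested. The count was 5 and 14 without replicate 1 and 2 of the label fkh2Δ, and 23 and 4 without those of the label fkh1Δ. ARS305 did not pass (0.33, adjusted p = 0.499), but did without replicate 2 of the label fkh2Δ (0.70) and without replicate 1 of the label fkh1Δ (0.64). ARS607 (0.35, adjusted p = 0.263) and ARS1 (−0.01, adjusted p = 0.988) did not pass. Windows near chromosome ends had a median of −0.24 with 0 of 42 called (0.000416; adjusted p = 0.604 with an estimated correlation), and −0.06 without replicate 1 of the label fkh2Δ, which ended the call. Those near centromeres had 0.03, with −0.16 and 0.24 without replicate 1 and 2 of the label fkh2Δ, each then past the threshold.

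A planned comparison of the label fkh1-dsm fkh2Δ with fkh1Δ set 2 groups that both held FKH1 by coverage. ARS305 was higher by 2.72 (edgeR adjusted p = 2.15e-09) and ARS607 by 2.05 (1.01e-09), and ARS1 did not pass (−0.18, adjusted p = 0.397), except with quantile normalization (−0.48). The window at 1050951 on chromosome XV rose most (4.52) and that at 410101 on chromosome XIV fell most (−3.32). Of 328 windows 248 passed, 118 higher and 130 lower, with 40 of 42 windows higher near chromosome ends (median 2.42) and 33 of 56 lower near centromeres (−0.61). Neither class passed with an estimated correlation (camera adjusted p = 0.254 near ends and 0.315 near centromeres). The matching comparison of FKH2-holding groups, the label fkh2-dsm fkh1Δ against fkh2Δ, was added after coverage was seen. It had ARS305 higher by 1.39 (1.96e-05) and ARS607 by 1.90 (2.12e-08), with 203 windows past the threshold, 93 higher and 110 lower, and 38 of 42 higher near chromosome ends (median 1.14). There too the windows near ends did not pass with an estimated correlation (camera adjusted p = 0.254). Profiles of the labels fkh1Δ and fkh2Δ correlated at 0.949 to 0.984 across windows, close to replicates of one label (0.977 to 0.996), while the label fkh1-dsm fkh2Δ correlated with them at 0.503 to 0.588 and the label fkh2-dsm fkh1Δ at 0.829 to 0.864.

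The 4C comparison of the label fkh1-dsm fkh2Δ with fkh2Δ asks which regions meet ARS305 in the nucleus. Windows near centromeres of other chromosomes took 10.24% and 9.17% of the counts outside the bait region under the label fkh2Δ and 6.05% and 6.57% under the label fkh1-dsm fkh2Δ, where they make up 7.49% of the tested genome. Their median log2 fold change was −0.58 (camera adjusted p = 4.7e-05; adjusted p = 0.354 with an estimated correlation; exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). Origin windows on other chromosomes took 31.95% and 24.69% against 22.56% and 24.46% (median −0.35, adjusted p = 0.000971; adjusted p = 0.354 with an estimated correlation), and the more strongly labelled of these 20.64% and 13.55% against 12.20% and 13.24% (−0.55, 2.4e-06; adjusted p = 0.354 with an estimated correlation). Windows near chromosome ends took 5.84% and 5.25% against 6.99% and 6.79% (adjusted p = 0.457), and chromosome III outside the bait region 1.91% and 2.08% against 2.16% and 1.67% (adjusted p = 0.666, exact permutation p = 1). Without replicate 1 of the label fkh2Δ none of the classes passed (0 of 5), and the medians were −0.21 near centromeres, −0.02 for origin windows and −0.13 for the more strongly labelled ones. Of 1189 windows 0 passed in edgeR, with the block or in DESeq2, and 90 had an unadjusted p under 0.05.

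These libraries hold few counts away from the bait. Between 97.22% and 98.77% of counts lay within 20 kb of it, leaving 39643 to 122664 counts and a median of 32 per window. The strains' forkhead genes could not be read from them. Their labels also conflict: the strain name given for the 4C libraries labelled fkh1-dsm fkh2Δ is the one that the RNA libraries labelled fkh2-dsm fkh1Δ carry. The genotype of these 4C libraries is therefore in doubt.

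**Figure D4:**
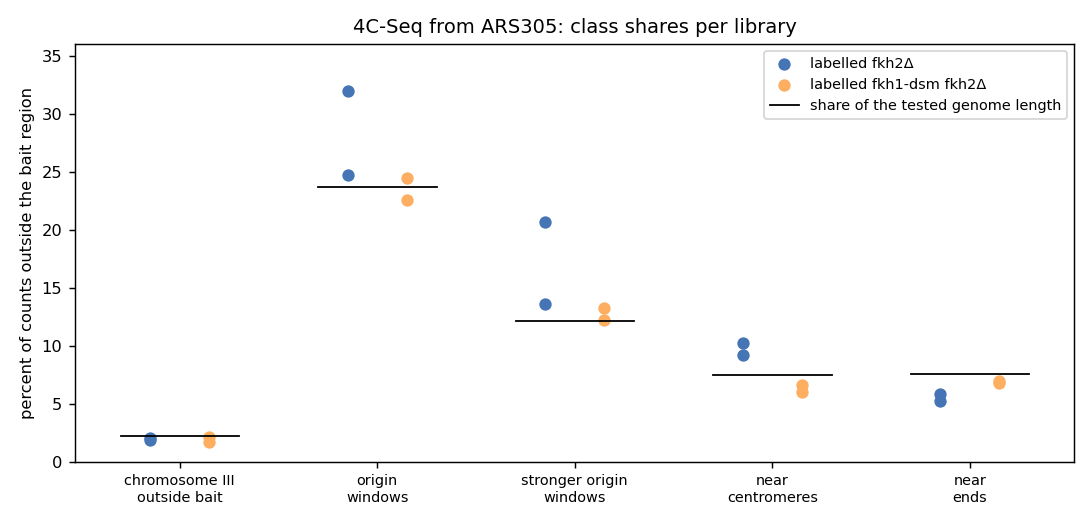
Percent of 4C counts outside the bait region in 5 window classes for each of the 4 libraries, with a line at each class's share of the tested genome. Near centromeres both libraries labelled fkh2Δ (10.24% and 9.17%) lie above both labelled fkh1-dsm fkh2Δ (6.05% and 6.57%).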

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

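Of the tests in this part, the one on repeats was written before its result was seen, and those on scaling, depth and the ribosomal DNA after.

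The effects of the dsm labels differed from each other in BrdU-IP-Seq. A test of the difference itself found 126 of 328 windows, with ARS305 (log2 difference 2.0) and ARS607 (0.84) larger under the label fkh1-dsm fkh2Δ. By coverage that contrast set FKH1 against FKH2 and the other set FKH2 against FKH1, so the difference does not compare alleles on a common background. With the deletion labels exchanged, a contrast added after coverage was seen, it was 1.33 for ARS305 and 0.15 for ARS607 (edgeR adjusted p = 0.00132 and 0.576), and 141 windows passed.

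The ribosomal DNA on chromosome XII lies outside the tested windows, and its share of the BrdU counts was above that of the deletion labels in all 4 dsm libraries. Its share was 6.75% ± 0.24 under the label fkh1-dsm fkh2Δ and 19.4% ± 0.304 under the label fkh2-dsm fkh1Δ. It was 3.72% ± 0.757 under the label fkh2Δ and 3.04% ± 0.233 under the label fkh1Δ, each with n = 2. A test was added after these shares were seen, with the ribosomal DNA as 1 more feature beside the windows in edgeR. For fkh2-dsm fkh1Δ over fkh1Δ the log2 fold change was 2.67 (SE 0.38, edgeR adjusted p = 2.53e-05) scaled by nuclear totals and 2.89 (adjusted p = 0.00014) with TMM. For fkh1-dsm fkh2Δ over fkh2Δ it was 0.86 (SE 0.36, edgeR adjusted p = 0.0411) scaled by nuclear totals but 0.70 (adjusted p = 0.144) with TMM, so that call depends on the scaling.

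Windows near chromosome ends rose under both dsm labels, with medians of 2.37 and 1.34. As a class they did not pass with an estimated correlation (camera adjusted p = 0.38 in both contrasts). For the rise, 3 technical explanations were weighed. Scaling does not account for it, since the lower median was still 1.31 with library totals. For repeated sequence, the median 15 to 30 kb from an end, where repeats are fewer, was 1.51 and 1.01, which met the condition written beforehand for excluding it. That band holds 2 windows, so a condition on its lower quartile was added afterwards, and with it repeats and a biological rise cannot be told apart. For depth, a first test compared the gap between replicates with the gap to the deletion libraries and decided nothing, at 0.0875 and 1.34.

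A second depth test, written after that, compared libraries of similar depth. The share of window counts near ends was 12.56% in replicate 2 of the label fkh1-dsm fkh2Δ against 3.98% in replicate 1 of the label fkh2Δ, a ratio of 3.16. It was 7.23% in replicate 2 of the label fkh2-dsm fkh1Δ against 3.04% in replicate 2 of the label fkh2Δ, a ratio of 2.38. Depth therefore does not account for the higher share in these 2 pairs, in a test written after the shares could be seen. The second pair does not use the label fkh1Δ of its contrast. Libraries of that label had 3.20% and 2.87%, at depths less close to the dsm library. The biological explanation, the dsm alleles, was not separated from other differences between the strains. Which BrdU libraries hold a dsm allele is known from the labels alone, and 4 of the 8 went against their label by coverage.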

How the results depend on the processing

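Of the values compared per gene, list or window, 6743 stayed on their side of the threshold, 273 lost and 236 gained a call, and 20 reversed. A value without a call in both fits counts as having stayed, so this tally does not measure how stable the calls were. Among the counts of calls, 166 stayed within 1.5 times and 92 moved. BrdU counts of the 2 dsm contrasts stayed at 205 to 245 and 143 to 194 with any library left out, and 4C windows at 0. A lone library left in a group is assumed to vary like the other groups. The cause was not tested for any result that changed, and fewer libraries also mean fewer degrees of freedom. In RNA-Seq, leaving out 1 library also unbalances the replicate numbers between the groups. The 4C windows have a median of 32 counts, and their replicates also spread beyond counting error (chi-square per degree of freedom 14.5 and 7.42). Which of these limits the calls was not tested. The shallowest RNA libraries are fkh2Δ replicate 2 and double deletion replicate 2, and the shallowest BrdU libraries fkh1Δ replicate 2 and fkh2-dsm fkh1Δ replicate 1. Leaving out the shallowest libraries, and 4C windows of 5 and 20 kb, were added after the data were seen. XbaI fragments and forkhead motif classes were not run, for lack of a genome sequence.

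RNA calls for fkh1-dsm fkh2Δ over fkh2Δ, fkh2-dsm fkh1Δ over fkh1Δ, the double deletion over fkh2Δ and over fkh1Δ, and the 2 dsm labels over the double deletion were 1, 1, 3, 3, 4 and 6. With 1 library left out they ranged over 0 to 1 in each of the first 4 and 0 to 3 in each of the others. With the 2 shallowest libraries out all were 0. DESeq2 gave 3 in the second, then 23, 23, 22 and 19. Genes extended past their 3′ end gave 0 and 0 in the first 2, 5 for the double deletion over fkh1Δ and 2 for fkh2-dsm fkh1Δ over the double deletion. The dsm labels against each other went from 0 to 2 in DESeq2.

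The replicate block gave 2, 44, 31, 35 and 21 RNA calls in all but the first of these, and 2 between the dsm labels. It gave 30 lists against 28. In BrdU the samples share only a number, with correlations of −0.75 to 0.79, and the replicate block gave 234, 185, 12, 238, 120 and 187 windows for the 2 dsm contrasts, fkh1Δ over fkh2Δ, fkh1-dsm fkh2Δ over fkh1Δ, the difference and the added contrast. In 4C, at −0.03, it gave 0.

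BrdU fkh1Δ over fkh2Δ went from 8 windows to 18 with library totals, 14 with quantile normalization and 4 with 2 kb windows, and ranged over 4 to 23 with 1 library left out. No minimum density gave 490, 427, 123, 612 and 218 windows in the planned BrdU contrasts. An estimated correlation left 2 of 28 RNA lists, 0 of 4 BrdU classes and 0 of 3 4C classes. With 1 library left out the RNA lists ranged over 15 to 34 and the 4C classes over 0 to 3.

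A list counts as reversed where its camera direction turned and it passed before or after. The median need not change sign with it, and other medians changed sign without it. The medians of reversed lists are given as their range with 1 library left out. For fkh1-dsm fkh2Δ over fkh2Δ: G1/S targets −0.30 to 0.27, stress response −2.88 to 1.92 (also 0.56), ribosome biogenesis −0.87 to 0.47 (also 0.27), glucose-repressed genes −1.05 to 0.79 (also 0.55). With the 2 shallowest libraries out G1/S targets and ribosome biogenesis were 0.27 and 0.47. For fkh2-dsm fkh1Δ over fkh1Δ: G1/S targets −0.43 to 0.17 (also 0.02), meiosis genes 0.02 to 1.11, stress response −1.61 to 2.5 (also −0.67), ribosome biogenesis −1.04 to 0.21, glucose-repressed genes −0.64 to 0.79 (also −0.47). For the double deletion, stress response −1.01 to 2.57 (also −0.54) over fkh2Δ and −0.68 to 2.48 (also −0.44) over fkh1Δ, and glucose-repressed genes −0.10 to 0.99 over fkh1Δ. For BrdU fkh1Δ over fkh2Δ, windows near centromeres −0.16 to 0.24.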

Other observations

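Of the tests in this part, the one on general amino acid control was written before its result was seen, and all others after.

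Genes of branched-chain amino acid and leucine synthesis stood higher in the double deletion. The 11 genes had median log2 fold changes of 1.51 against the label fkh2Δ and 1.09 against the label fkh1Δ, and 6 and 5 rose when adjusted over the list alone (camera adjusted p = 0.00136 with an estimated correlation in both). The list was drawn up after LEU1, BAT1 and OAC1 had been seen to rise, so it is no independent evidence. The 28 other amino acid synthesis genes had medians of 0.63 and 0.43, with 27 above 0 in each (camera adjusted p = 0.0454 and 0.123 with an estimated correlation). In the first, the block and an estimated correlation together gave a camera adjusted p of 0.128, which ends that call.

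General amino acid control by Gcn4 would raise both sets alike. The branched-chain median lay above the other by 0.87 (bootstrap SE 0.62) and 0.66 (SE 0.51). Whether the branched-chain genes rose beyond what Gcn4 would give therefore cannot be told. Higher values were not confined to the leucine pathway, since 27 of the 28 other genes lay above 0 in each comparison. A LEU2 marker gained or lost in the double deletion does not account for the rise, since LEU2 differed by 0.07 and −0.02 on the log2 scale (SE 0.29). A LEU2 allele that is transcribed but not functional would not show in this test.

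The coverage of FKH1 and FKH2 ran against the labels in 8 libraries, which a mislabelled sample would produce. Reads shared between the paralogs do not account for it in the RNA libraries labelled fkh2Δ, since FKH1 had 0 counts over both although FKH2 was present. A mixed sample does not either in those libraries, where FKH1 had 0 counts. The floor of 3 bin counts, which is no strict upper limit, came to at most 2.78% of the lowest RNA library that held FKH1. Neither test covered the other libraries that went against their label. In the BrdU libraries labelled fkh2Δ, FKH1 kept 0.0667 and 0.0503 of the density of its flanks. Whether the strains or the file names were exchanged was not tested, and no biological explanation was tested.

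Coverage of FKH2 outside its 3′ part was raised in all 8 BrdU libraries, at 1.20 to 4.22 of the flanks. In RNA the same part stood at 135 and 54.7 CPM under the label fkh1-dsm fkh2Δ and at 0.560 and 0.0563 CPM under the label fkh2-dsm fkh1Δ. TRP1 was 74.6 CPM in replicate 1 and 12.6 CPM in replicate 2 of the label fkh2Δ, and URA3 was 1570 and 669 CPM. MF(ALPHA)1, which encodes alpha-factor, had 74 counts in replicate 1 of the double deletion and 0 in replicate 2. Mitochondrial DNA took 14.6% to 54.8% of BrdU counts, with 32.3% and 54.8% in the replicates labelled fkh1Δ.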
